A study of Mus musculus with 16 samples.

How the data were processed

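RNA was measured in 16 libraries of Ba/F3 cells, an interleukin-3-dependent mouse pro-B cell line, in 4 groups of 4. One line carried gp130 and the interleukin-6 receptor (gp130:IL-6R), and the other carried a receptor labelled ChimP3V3:gp130Box1/2 (called ChimP3V3 here). Each line was kept in medium or given interleukin-6 (IL-6) at 100 ng/ml. The time under IL-6 was not given in the sources used here. The sample titles and IL-6 doses do not record whether interleukin-3 was present in either condition. Changes under IL-6 are therefore differences between these conditions as labelled. Per the labels' protocols, RNA was isolated on silica columns (NucleoSpin RNA), 100 ng of total RNA entered the Lexogen QuantSeq forward kit, which sequences the 3' ends of polyadenylated RNA, and single reads of 100 bases were made on a NextSeq2000. No molecular identifiers were named.

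The deposited table gave raw counts per gene for 25650 genes, which the authors made with CLC Genomics Workbench 23.0.4 on genome build GRCm39 with Ensembl release 107, per the file headers and the overview sheet. The read filters, the treatment of reads that share a position and the strand setting of the counting were not given in the sources used here. The deposited log2 fold changes and p-values of the authors' own comparisons were used only for counts of genes past the authors' thresholds. The 48 deposited columns of RPKM, TPM and CPM per library were not used. Coordinates are those of the deposited table, on GRCm39; the reference genome at hand was of an earlier build and was not used. The kit marks strand, but without the strand setting the counts of overlapping and antisense genes are uncertain. Counts of near-identical copies, such as the globin genes, are also uncertain because reads can fit more than 1 copy.

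Of the 25650 genes, 10566 had 0 counts in every library and 15084 had at least 1 count. Genes were kept with filterByExpr by group (minimum count 10, minimum total 15), which left 9540 genes holding 99.6% of all counts. Libraries were scaled with TMM factors, and CPM values were computed with these factors. A quasi-likelihood model (glmQLFit and glmQLFTest, edgeR 4.0.16 in R 4.3.3) was fitted to all 16 libraries with 1 mean per group, which left 12 residual degrees of freedom. The comparisons were IL-6 against medium in each line, the difference of these responses (ChimP3V3 minus gp130:IL-6R), and ChimP3V3 against gp130:IL-6R cells in medium and under IL-6. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values of single genes come from this edgeR model unless another tool is named. Folds and log2 values are the model's estimates with their standard error (SE); n is 4 libraries per group throughout.

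The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named 15 genes tied to IL-6 signalling whether called or not. It also named the 8 largest rises and 8 largest falls per response and between the lines in medium, among genes with a mean CPM of at least 5 and no overlap between the 4 libraries of each group. For the difference of responses it named the 8 smallest p-values in each direction, and for each called list up to 4 members with the smallest p in its direction. Predicted genes, clones, pseudogenes and ribosomal protein genes were counted but not named by it. List members named because 5 or fewer of a list rose or fell, and genes between the lines under IL-6, were chosen after their values were seen. Results of some genes are not reported here. Among 4 against 4 libraries of the same kind, chance gives no overlap in 2.86% of genes.

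The 22 gene lists, taken from general knowledge and not from these samples, were tested with camera (limma 3.58.1, preset correlation 0.01, two-sided) in 4 comparisons, with adjustment over the lists of a comparison. Lists with fewer than 3 tested members had no such test. The list called erythroid markers here holds both erythroid and megakaryocyte markers. The tests were repeated with an estimated correlation and with fry, which asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. Library measures were compared by two-sided exact permutation tests, whose smallest p for 4 against 4 libraries is 0.0286, with adjustment over 20 tests.

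Alternatives were RLE and upper-quartile factors, no filter, a CPM of at least 5 in 4 libraries, only the groups compared, a replicate block, DESeq2 1.42.0, limma on log2(CPM + 1), an adjusted p under 0.01, a fold of at least 1.5, and each library left out. Added after the data were seen were merged replicates, counts thinned to the smallest library total of 1275112, and removal of genes with a mean count over 800. Other splits of the libraries were drawn with a fixed seed, at most 100 per comparison. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and plots.

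The tests were tested on simulated data with 200 changed genes. Apart from a shifted gene list, the other genes had the same mean in all groups, and abundant counts were not limited. The real libraries had many more called genes, so the rates below need not hold for them. For the IL-6 response of gp130:IL-6R cells (9369 genes), edgeR recovered 77.6% of 1.5-fold, 96.9% of 2-fold and 97.0% of 3-fold changes and called 11 unchanged genes. For ChimP3V3 cells (9370 genes) it recovered 73.8%, 86.6% and 96.9% and called 12. For the difference of responses (9371 genes) it recovered 54.5%, 74.2% and 89.2% and called 11. Between the lines in medium (9372 genes) it recovered 70.1%, 97.0% and 98.5% and called 17. Between the lines under IL-6 (9383 genes) it recovered 71.2%, 82.8% and 98.5% and called 13.

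A simulated list shifted by a log2 value of 0.5 was recovered by camera in every comparison, with adjusted p from 3.39e-19 to 9.89e-10, and at most 1 unshifted list was called.

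Nothing in the labels says that the 4 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Some replicate pairs did not differ beyond sampling noise over all genes. Over genes with 20 to 200 counts per pair all 24 pairs differed, but by little (median chi-square per degree of freedom 1.11). The model's common coefficient of variation between replicates, beyond counting noise, was 1.59%. These values do not show that the 4 libraries of a group were independent cultures. All 4 were counted as replicates, and p-values may be too small if they were not independent. A count of 0 over a group was given a floor of 3 counts over that group's 4 libraries, and bounds divide the mean CPM by this floor on the same TMM-scaled totals. Intervals (95%) and floors cover counting error only, since reads without molecular identifiers are not independent molecules.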

Results

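Ba/F3 cells, a mouse pro-B line that grows on interleukin-3, carried either gp130 with the IL-6 receptor (gp130:IL-6R cells) or the ChimP3V3 receptor. The series title describes synthetic receptors for IL-6 whose activity is mainly phosphorylation of STAT3. Each line was sequenced in medium and under IL-6, with 4 libraries per group and 16 in all. Total counts per library ranged from 1275112 to 1650348, and a count of 0 in 1 library allows a level of up to 1.80 to 2.41 CPM. Between 10968 and 11539 genes had a count in a library.

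Mitochondrial genes (13 genes) and ribosomal protein genes (79 genes) took a larger share of the counts under IL-6 in both lines. The mitochondrial share rose from 1.16% ± 0.024 to 1.53% ± 0.078 (SD, n = 4) in gp130:IL-6R cells and from 1.40% ± 0.035 to 1.69% ± 0.042 in ChimP3V3 cells (exact permutation p = 0.0286, adjusted p = 0.0381 for each). The ribosomal protein share rose from 5.86% ± 0.171 to 6.76% ± 0.194 (SD, n = 4) and from 6.45% ± 0.112 to 7.28% ± 0.147 (exact permutation p = 0.0286, adjusted p = 0.0381 for each). Both shares were also higher in ChimP3V3 than in gp130:IL-6R cells in medium (exact permutation p = 0.0286, adjusted p = 0.0381 for each). Mean total counts were lower under IL-6 in ChimP3V3 cells, 1339405 ± 52853 against 1449201 ± 47585 (SD, n = 4, exact permutation p = 0.0286, adjusted p = 0.0381). The 10 most abundant genes held 1.52% to 1.81% of the counts in the mean of a group. Within groups, summed counts of the 227 genes with a mean count over 800 grew less than in proportion to library totals. The log-log slope was 0.645 (SE 0.0409). Fold changes of abundant genes, ribosomal protein genes among them, may therefore be too small, and their shares may rise where totals are lower. For less abundant genes the slope was above 1, at 1.52 for mean counts of 1 to 10 and 1.13 for 100 to 300. Levels of these genes may thus also depend on library totals. Within the gp130:IL-6R medium and ChimP3V3 IL-6 groups, the ribosomal protein share rose with each fall of the total, and less strictly in the others. Differences in share between groups may thus come in part from library totals. In gp130:IL-6R cells, mean totals were 1541373 in medium and 1495946 under IL-6 (exact permutation p = 0.457, adjusted p = 0.481), and their ranges overlapped. The ribosomal protein shares there did not overlap, at 5.63% to 6.01% and 6.58% to 7.03%. This argues against totals as the whole cause of that rise in this line.

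The receptor genes were read first. Il6st, which encodes gp130, lies on chromosome 13 from 112600604 to 112646620 (plus strand) and had 181 to 235 counts per gp130:IL-6R library in medium and 255 to 278 under IL-6. It had 0 counts in all 8 ChimP3V3 libraries, which allows up to 0.506 CPM over the medium group and 0.570 CPM over the IL-6 group. Il6ra, which encodes the IL-6 receptor, had 3 counts in all, 1 each in 3 gp130:IL-6R libraries under IL-6, and was not tested. The counts carry no label that separates an introduced mouse gene from the cell's own.

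The first comparison asked which transcripts changed when gp130:IL-6R cells received IL-6. Socs3 (ENSMUSG00000053113), a feedback inhibitor of JAK-STAT signalling (chromosome 11, 117856905 to 117860873, minus strand), rose 6.64-fold, from 21.9 ± 3.57 to 146 ± 17.2 CPM (SD, n = 4, log2 2.73, SE 0.111, adjusted p = 3.47e-23). Fos, a subunit of the AP-1 transcription factor (chromosome 12, 85520664 to 85524047, plus strand), rose from 0.638 ± 0.494 to 59.5 ± 8.9 CPM (SE 0.28 on the log2 scale, adjusted p = 5.94e-22). Junb, another AP-1 subunit (chromosome 8, 85701113 to 85705347, minus strand), rose 3.20-fold, and the kinase gene Pim1 (chromosome 17, 29709727 to 29715086, plus strand) rose 1.47-fold. Cdk6, a cell-cycle kinase gene (chromosome 5, 3391485 to 3581008, plus strand), fell from 602 ± 16.9 to 409 ± 16.8 CPM (SD, n = 4, log2 -0.56, SE 0.0377, adjusted p = 4.32e-16).

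The largest rises after Fos were in Cox6a2, Fosb, Socs1, S100a4, Adam8, Rusc2 and Anxa1. S100a4, a calcium-binding protein gene, rose 9.50-fold from 10.7 to 101 CPM. Anxa1, which encodes annexin A1, rose 7.79-fold and Adam8, a metalloprotease gene, 8.52-fold. Socs1 had few counts in medium, and its ratio was 19.9 (95% counting interval 5.14 to 170.0); that of Cox6a2 was 54.4 (9.34 to 2189). The largest falls were in Fam216a, Aldh1a1, Lgals9, Fry, Klf1, Thop1, H2bc12 and Arhgap19. Aldh1a1, a retinaldehyde dehydrogenase gene, was 4.83-fold lower under IL-6 and Klf1, an erythroid transcription factor gene, 2.84-fold lower.

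Of the other genes named in advance, Myc rose 1.96-fold, Dusp6 1.80-fold, Il6st 1.32-fold and Spred1 1.20-fold (adjusted p = 3.34e-10, 2.23e-11, 1.17e-06 and 0.00486; n = 4). Cish rose by 0.74 on the log2 scale (SE 0.304, adjusted p = 0.0408), a call that was lost with DESeq2 (adjusted p = 0.0881) and limma (0.0704). It was also lost without medium replicate 2 (adjusted p = 0.118), 3 (0.0541) or 4 (0.083) and without IL-6 replicate 2 (0.0772) or 4 (0.239). The call of Spred1 was lost without medium replicate 3 (adjusted p = 0.0828). Stat3 (log2 0.06, adjusted p = 0.302) and Irf1 (log2 -0.01, adjusted p = 0.935) did not pass the test. Bcl3 and Egr1 had too few counts to be tested.

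Immediate-early and feedback genes of the ERK pathway rose together in gp130:IL-6R cells. Of 22 tested members 20 rose and none fell, with a median log2 change of 1.44 (camera adjusted p = 6.99e-21; 21 rose adjusted over the list alone). Dusp1, a phosphatase gene that limits MAP kinases, rose 4.25-fold and Ier3 2.23-fold. Of 23 STAT3 targets and feedback genes 13 rose and none fell (adjusted p = 1.90e-09). Among 16 STAT5 and IL-3 targets 11 rose, with oncostatin M (Osm) up 4.81-fold and granzyme B (Gzmb) 2.23-fold, and Ccnd3 fell (adjusted p = 2.77e-05). Of 37 interferon-stimulated genes 14 rose, among them Irgm1 (2.87-fold) and Trim25 (2.00-fold), and Psmb10 and Eif2ak2 fell (adjusted p = 0.0120).

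Cell cycle genes fell: 45 of 50 were lower and 2 higher (median log2 -0.55, camera adjusted p = 7.47e-26; 46 lower adjusted over the list alone). Mcm2, a replication helicase gene, was 2.19-fold lower and Ccna2, which encodes cyclin A2, 1.68-fold lower. Of 24 cholesterol synthesis genes 19 fell and 1 rose (adjusted p = 2.54e-11), with Fdps 2.37-fold lower. Of 47 MYC and ribosome biogenesis genes 31 fell and 6 rose (adjusted p = 2.77e-05; 32 fell adjusted over the list alone), and of 15 heat shock genes 8 fell while Hspa8, Dnajb1 and Dnaja1 rose (adjusted p = 0.00499). These falls stood beside the larger mitochondrial and ribosomal protein shares of the same libraries.

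Of 28 glycolysis and hypoxia genes 20 rose and Pfkfb4 fell (camera adjusted p = 3.34e-08), with Ndrg1 up 2.27-fold. Of 23 p53 targets 13 rose and none fell (adjusted p = 2.77e-05), with Trp53inp1 up 4.15-fold and Cdkn1a, a cyclin-dependent kinase inhibitor gene, up 1.58-fold. Of 18 FOXO targets 12 rose and Tsc22d3 fell (adjusted p = 0.000398), with the pro-apoptotic gene Bcl2l11 up 1.91-fold. Of 17 NF-kB targets 8 rose and Nfkb1 fell (adjusted p = 0.000563), with Nfkbia up 2.59-fold. Of 23 integrated stress response genes 10 rose and Shmt2 and Mthfd2 fell (adjusted p = 0.00158), with Trib3 up 2.50-fold.

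Of 22 ER folding genes 11 rose, with Dnajb9 up 3.05-fold, and Dnajb11, Hsp90b1, Manf and Creld2 fell (camera adjusted p = 0.00634; adjusted p = 0.0529 with an estimated correlation; 11 rose and 5 fell adjusted over the list alone). Of 16 mast cell, basophil and myeloid progenitor markers 10 rose and Gata1 and Ms4a3 fell (adjusted p = 0.0132). Lists not called were BCL2 family and apoptosis (6 higher and 6 lower of 25, adjusted p = 0.808), receptors and signalling proteins of the cultures (9 and 5 of 23, 0.214), pro-B markers (Cd79a higher and Tcf3 lower of 3, 0.724), macrophage and dendritic cell markers (Lyz2 and Spi1 higher and Ccr2 lower of 5, 0.822) and erythroid markers (Hba-a2 and Itga2b higher, Gata1, Klf1 and Tfrc lower of 10, 0.685). The medians of the last 3 lists were negative and their means positive; with genes at 0 set to their bounds, the medians of the macrophage and erythroid lists were 0.06. T and NK markers (Gzmb higher of 2) and fibroblast and epithelial markers (Vim higher of 1) had too few members for camera. Unless given, counts adjusted over the list alone were equal to those over all genes.

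In all, 4769 of 9540 genes were called for this response, 2454 higher and 2315 lower, and 1558 of them changed at least 1.5-fold (995 higher, 563 lower). The authors' deposited table holds 1636 genes at an FDR of at most 0.05 and at least 1.5-fold, 1072 higher and 564 lower. Junb overlaps Prdx2, and Dusp1 overlaps Ergic1, on the opposite strand, so that some of their counts are uncertain.

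The second comparison asked the same of ChimP3V3 cells. Socs3 rose 5.22-fold, from 12.7 ± 3.14 to 66.4 ± 4.34 CPM (SD, n = 4, log2 2.39, SE 0.158, adjusted p = 1.44e-15), and Pim1 3.04-fold, from 119 ± 8.49 to 360 ± 6.16 CPM (adjusted p = 7.21e-26). Junb rose 1.46-fold and Osm 3.46-fold. Fos fell, from 23.6 ± 1.12 to 12.9 ± 1.47 CPM (log2 -0.87, SE 0.195, adjusted p = 0.000577), and Fosb fell by 3.14 on the log2 scale (SE 0.366, adjusted p = 6.6e-09). Cdk6 rose from 427 ± 13.0 to 712 ± 14.8 CPM (log2 0.74, SE 0.0371, adjusted p = 1.48e-19).

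Several of the largest rises were in globin genes. The embryonic globin genes Hba-x, Hbb-bh1 and Hbb-y rose 15.3-fold, 7.97-fold and 4.82-fold, and Hbb-y reached 237 ± 9.43 CPM (SD, n = 4). The adult globin gene Hbb-bs (chromosome 7, 103475741 to 103477303, minus strand) rose 2.67-fold, from 321 ± 16.6 to 859 ± 27.1 CPM. Socs1, H2ac6, Slc6a20a and Ier3 were also among the largest rises, the last 4.46-fold. The largest falls were in Fosb, Zswim4, Cd69, Rgcc, Angptl2, Rapsn, Lurap1 and Rad51c, and Cd69, an activation marker of lymphocytes, was 4.08-fold lower.

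Of the genes named in advance, Myc rose 1.53-fold and Dusp6 1.45-fold (adjusted p = 7.45e-06 and 0.000351; n = 4). Cish rose by 0.87 on the log2 scale (SE 0.294, adjusted p = 0.0227; 0.067 with DESeq2), and the call was lost without medium replicate 1 (adjusted p = 0.0836) or 2 (0.11) and without IL-6 replicate 2 (0.085) or 3 (0.0799). Irf1 rose 1.22-fold (adjusted p = 0.0195), a call lost with DESeq2 (adjusted p = 0.0843), without the filter (0.064) and with thinned counts (0.0585). It was also lost without medium replicate 3 (adjusted p = 0.0722) and without IL-6 replicate 1 (0.0734), 2 (0.107) or 3 (0.124). Spred1 (log2 0.20, adjusted p = 0.124) and Stat3 (log2 0.02, adjusted p = 0.84) did not pass the test, and Il6st had 0 counts.

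Of 23 STAT3 targets and feedback genes 11 rose and Fos fell in ChimP3V3 cells (camera adjusted p = 1.17e-05), and of 16 STAT5 and IL-3 targets 9 rose and none fell (adjusted p = 1.17e-05). ERK immediate-early and feedback genes went both ways, with 9 of 22 higher and Fos, Fosb, Ier5 and Dusp1 lower (adjusted p = 0.0626, not called). Of 18 FOXO targets 10 rose and Tsc22d3 fell (adjusted p = 1.89e-06), with Txnip up 1.76-fold and Gadd45a 1.80-fold. Of 28 glycolysis and hypoxia genes 18 rose and Slc2a3 and Pfkfb4 fell (adjusted p = 9.81e-11; 20 rose adjusted over the list alone), with the hexokinase gene Hk2 up 1.54-fold.

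Cell cycle genes fell in this line too: 43 of 50 were lower and Gins2, Ccnd2, Ccnd3 and Cdk6 higher (median log2 -0.49, camera adjusted p = 2.93e-29; 44 lower adjusted over the list alone). Cenpe, a centromere protein gene, was 1.60-fold lower and Birc5, which encodes survivin, 1.42-fold lower. Of 24 cholesterol synthesis genes 13 fell and none rose (adjusted p = 1.39e-05), with Cyp51 1.36-fold lower. The mitochondrial and ribosomal protein shares were larger in these libraries as well.

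Of 10 erythroid and megakaryocyte markers Hba-a1, Hba-a2, Hbb-bs, Hbb-bt and Itga2b rose and Tfrc fell (camera adjusted p = 1.45e-16). Adjusted over the list alone, 6 rose. Of 16 mast cell, basophil and myeloid progenitor markers 6 rose, among them the protease gene Cpa3 (3.59-fold) and the IgE receptor gene Fcer1a (4.38-fold), and none fell (adjusted p = 0.0133; 7 rose adjusted over the list alone). Of 17 NF-kB targets Nfkbiz, Tnfaip3, Il6, Ier3 and Tnip1 rose (adjusted p = 0.0133), a call that was lost without the filter (adjusted p = 0.151) and with the replicate block (0.0577).

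Lists not called in ChimP3V3 cells were p53 targets (6 higher and Ckap2 lower of 23, camera adjusted p = 0.209), interferon-stimulated genes (5 and 4 of 37, 0.794), MYC and ribosome biogenesis (9 and 9 of 47, 0.5), BCL2 family and apoptosis (7 higher and 3 lower of 25, 0.570) and the integrated stress response (6 and 5 of 23, 0.169). The same held for ER folding (6 and 4 of 22, 0.729), heat shock (4 and 2 of 15, 0.841), receptors and signalling proteins (6 higher and Stat5b lower of 23, 0.367), macrophage and dendritic cell markers (Ccr2 higher of 5, 0.427) and pro-B markers (0 of 3, 0.929). The median of the heat shock list was negative and its mean positive, and the MYC list had a positive median and mean with a test direction of lower. Gzmb of the T and NK markers was higher, and Vim, the single fibroblast and epithelial marker tested, was lower.

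In ChimP3V3 cells 2625 of 9540 genes were called, 1541 higher and 1084 lower, and 510 changed at least 1.5-fold (293 higher, 217 lower). The excess of rises depended on the settings: 1303 were higher and 1266 lower without the filter, and 1138 and 1158 without IL-6 replicate 3. The authors' deposited table holds 528 genes past its thresholds of FDR and 1.5-fold, 277 higher and 251 lower. The fall of Lurap1, from 8.26 to 3.20 CPM, did not pass the test without IL-6 replicate 2 (adjusted p = 0.0524). Reads of the globin genes can fit more than 1 copy, which makes their single values uncertain.

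**Figure D1:**
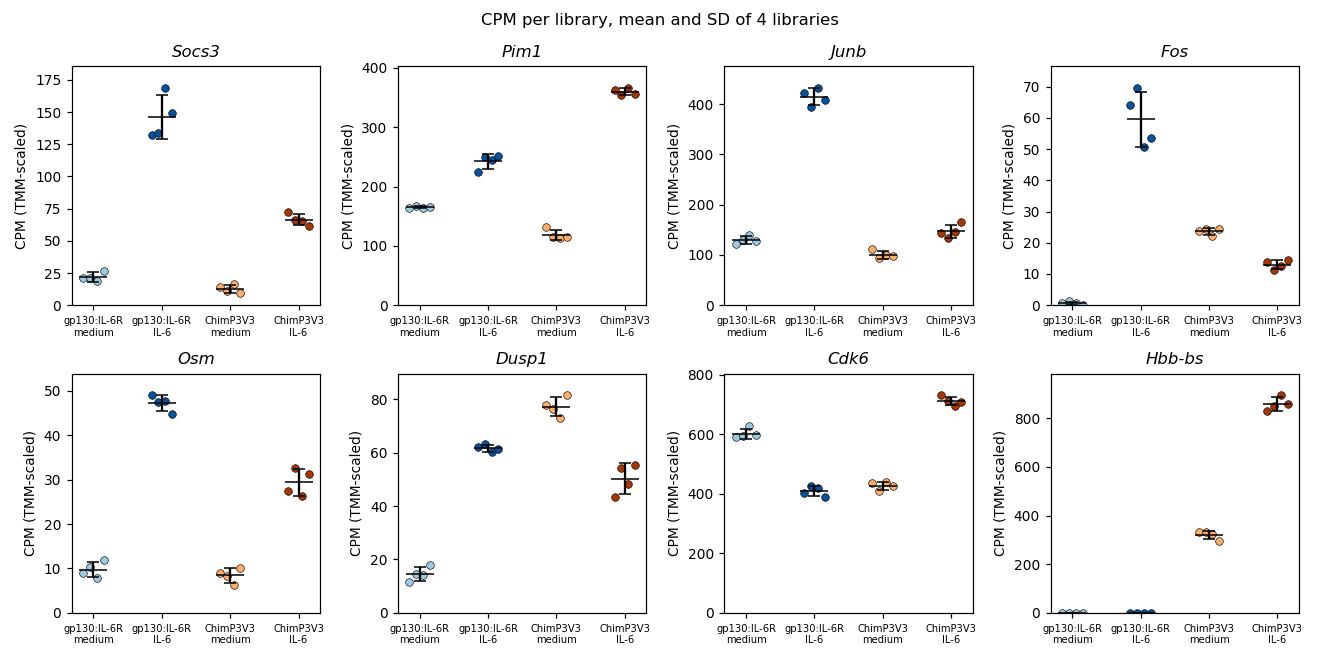
CPM of 8 genes in each library (points), with the mean and SD of the 4 libraries of each group (bars); each panel has its own linear axis from 0. Fos rose from 0.638 to 59.5 CPM under IL-6 in gp130:IL-6R cells and fell from 23.6 to 12.9 CPM in ChimP3V3 cells, whereas Socs3 rose in both.

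The third comparison tested whether the responses of the lines differed. Fos had the largest difference among the genes named in advance, with a response lower in ChimP3V3 cells by a log2 value of -7.20 (SE 0.38, adjusted p = 1.3e-18, n = 4). Junb (log2 -1.13, SE 0.0943, adjusted p = 1.66e-12) also responded less in ChimP3V3 cells. Pim1 responded more (log2 1.05, SE 0.0764, adjusted p = 3.38e-14), and so did Cdk6, which fell in gp130:IL-6R cells and rose in ChimP3V3 cells (log2 1.30, SE 0.0528, adjusted p = 4.47e-22). The difference for Socs3 did not pass the test (log2 -0.35, SE 0.23, adjusted p = 0.299), nor did those for Cish, Myc, Dusp6, Spred1, Stat3 and Irf1 (adjusted p from 0.0841 to 0.872). The difference passed for Irf1 without IL-6 replicate 2 of gp130:IL-6R cells (adjusted p = 0.0382) and for Myc without IL-6 replicate 2 of ChimP3V3 cells (adjusted p = 0.0437).

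The genes with the smallest p among lower responses in ChimP3V3 cells were Fos, Spp1, Klf6, S100a4, Sqstm1, Hexim1, Anxa1 and Vim. Spp1, which encodes osteopontin, went from 88.3 ± 4.46 to 361 ± 22.1 CPM in gp130:IL-6R cells and from 151 ± 12.9 to 153 ± 11.4 CPM in ChimP3V3 cells (SD, n = 4). Anxa1 differed by -3.23 and S100a4 by -2.70 on the log2 scale; both were more abundant in ChimP3V3 cells in medium, at 272 and 340 CPM. Higher responses were led by Cdk6, Atg12, Muc13, Col5a1, Gria3, Scin, Gpx1 and Pim1, and Gria3, a glutamate receptor gene, went from 41.8 to 98.1 CPM in ChimP3V3 cells.

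The ERK list responded less in ChimP3V3 cells: 12 of 22 members were lower and Ier3 and Maff higher (camera adjusted p = 4.43e-12). Adjusted over the list alone, 14 were lower. The median log2 difference was -0.90, or -0.79 without the 1 member that had 0 counts in a whole line. Dusp1 stood at -2.71. Lower responses were also found for 10 of 23 p53 targets, with Ptpn14 higher (adjusted p = 0.000159), for 9 of 23 integrated stress response genes (adjusted p = 2.20e-05; 11 adjusted over the list alone) and for 10 of 22 ER folding genes, with Calr higher (adjusted p = 0.000418; 11 lower and 2 higher adjusted over the list alone). Trp53inp1, Atf5 and Herpud1 led these lists, at -2.13, -1.28 and -0.87.

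Cholesterol synthesis genes had the higher (less negative) response in ChimP3V3 cells in 13 of 24 members and the lower in none (camera adjusted p = 1.56e-05; 15 adjusted over the list alone), with Fdps at 0.83 and Idi1 at 0.70. For MYC and ribosome biogenesis 18 of 47 were higher and Tfrc lower (adjusted p = 0.000141; 23 and 2 adjusted over the list alone). Heat shock genes were higher in 8 of 15, with Hspa8 and Dnaja1 lower (adjusted p = 0.00886; 9 and 2 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.0914). Cell cycle genes were higher in 13 and lower in 6 of 50 (adjusted p = 0.0261; 15 and 6 adjusted over the list alone), also lost with an estimated correlation (adjusted p = 0.352), without the filter (0.113) and with a CPM of at least 5 (0.0713).

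No difference was called for STAT3 targets (Pim1 higher, Junb, Fos, Cebpb, Cebpd and Mcl1 lower of 23, camera adjusted p = 0.0724), STAT5 and IL-3 targets (2 higher and 3 lower of 16, 0.970), interferon-stimulated genes (Psmb8 higher and 6 lower of 37, 0.116), FOXO targets (0.942), NF-kB targets (0.596), glycolysis and hypoxia (4 and 10 of 28, 0.580), mast cell markers (0.942) or erythroid markers (2 and 3 of 10, 0.735). Adjusted over the list alone, 5 glycolysis and hypoxia genes were higher and 11 lower. The median and mean differed in sign for the FOXO, NF-kB, glycolysis, mast cell and receptor lists. The test's direction went against both for the STAT5 and BCL2 lists. In all, 2280 genes were called for the difference, 1182 with the higher and 1098 with the lower response in ChimP3V3 cells, and 1006 differed at least 1.5-fold (394 higher, 612 lower). With the filter 51.8% of the called genes were higher, and without it 41.8% of 2160. The share lay between 41.6% and 42.9% without IL-6 replicate 1 or 4 of gp130:IL-6R cells or any 1 IL-6 replicate of ChimP3V3 cells. An adjusted p under 0.01 gave 1453 genes.

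**Figure D2:**
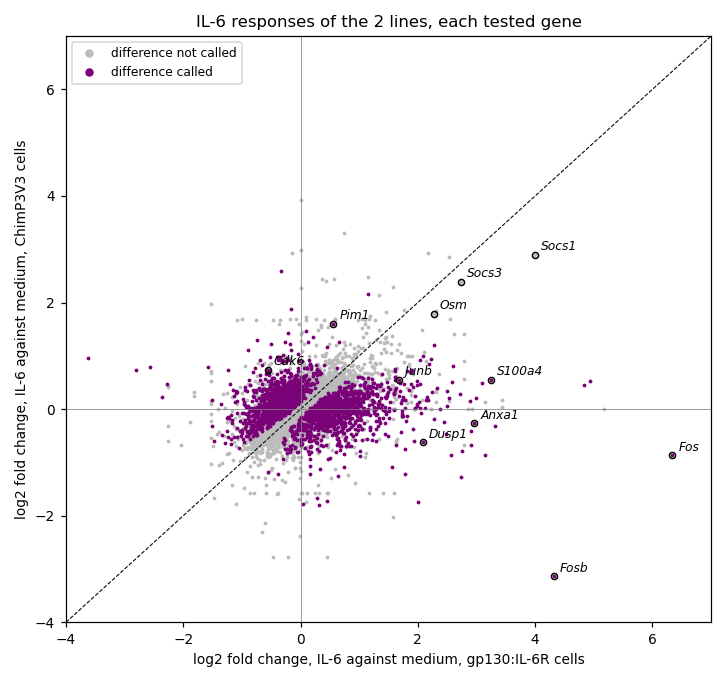
Log2 fold change of each of 9540 tested genes under IL-6 in gp130:IL-6R cells (x axis) and ChimP3V3 cells (y axis); 3 genes lie outside the axes, the dashed line marks equal responses, and purple points are the 2280 genes called for the difference. Fos, Fosb, Anxa1 and Dusp1 lie far below the line and Pim1 and Cdk6 above it.

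The size of the responses was compared over genes called for the mean of both lines, which favours neither line. Over 2475 genes that rose, the median log2 change was 0.42 (SD 0.00623 over the 4 IL-6 libraries) in gp130:IL-6R cells and 0.24 (SD 0.0117) in ChimP3V3 cells. The difference was called in 715 of them as lower and in 163 as higher in ChimP3V3 cells. Over 2106 genes that fell, the medians were -0.39 and -0.23, with 523 differences called higher and 86 lower.

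The called genes of the lines overlapped in the same direction. Both lines called 830 genes higher, where independent lists would share 396, and 727 lower, where 263 would be shared. Opposite directions were called in 218 genes, where 653 would be shared by independent lists; 74 were higher in gp130:IL-6R and lower in ChimP3V3 cells and 144 the reverse. Across genes, which are not independent replicates, the responses had a Pearson correlation of 0.28 and a Spearman correlation of 0.38.

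**Figure D3:**
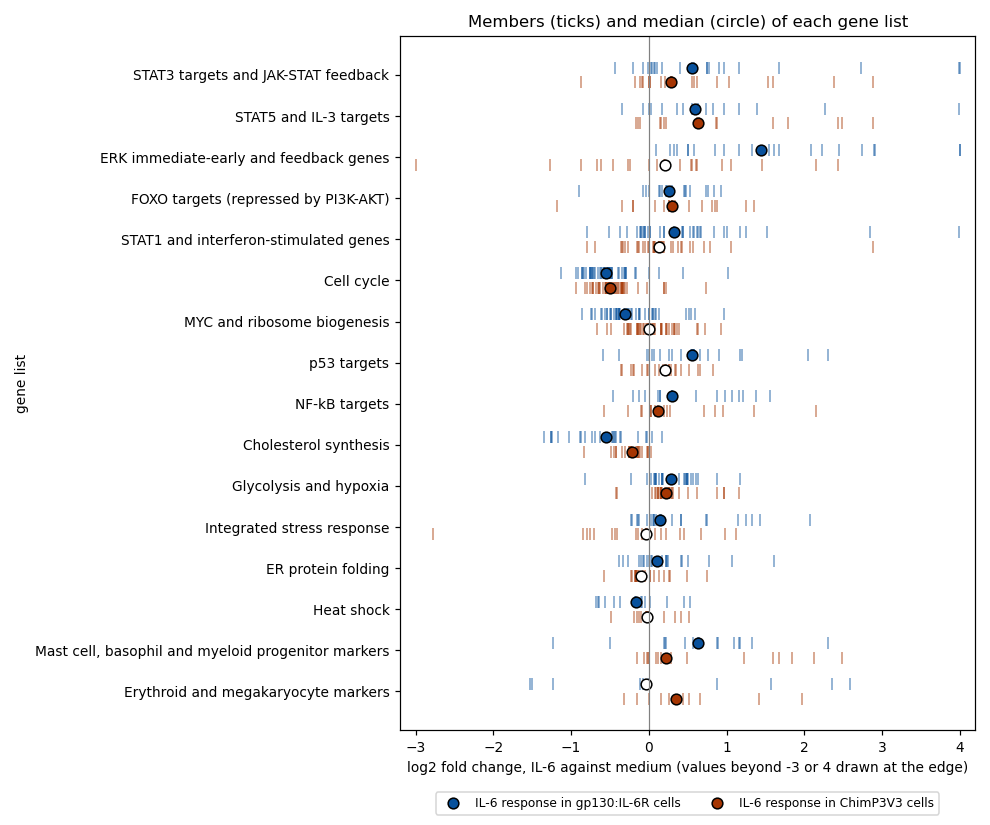
Log2 fold changes under IL-6 of the members of 16 gene lists (ticks) with their medians (circles) in gp130:IL-6R (blue) and ChimP3V3 cells (orange); a filled circle marks a camera adjusted p under 0.05. The ERK list has its median at 1.44 in gp130:IL-6R cells and at 0.20 in ChimP3V3 cells, whereas the cell cycle list lies at -0.55 and -0.49.

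The fourth comparison set the lines in medium against each other. Globin genes were high in ChimP3V3 cells: Hbb-bs stood at 321 ± 16.6 CPM (SD, n = 4) against 0 counts in gp130:IL-6R cells, at least 659-fold higher. Hba-a1 stood at 493 ± 40.5 CPM, with a ratio of 3034 (95% counting interval 544 to 119900). Rhag, an erythroid membrane protein gene, was at least 251-fold higher, and Plxdc2, Elf4, P2ry10, Abcb4 and Lcp2 were at least 146-fold higher. In the other direction Gdf3, a growth factor gene (chromosome 6, 122582362 to 122587046, minus strand), was at least 381-fold lower, and Hook1, Wfdc15a, Rbpms2, Fmr1, Il6st, Rnf217 and Il18rap were at least 209-fold lower.

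All 10 tested erythroid and megakaryocyte markers were higher in ChimP3V3 cells (camera adjusted p = 8.01e-32). Their median log2 difference was 4.75, or 4.05 with genes at 0 set to their bounds. The list summed to 2700 ± 74.9 CPM against 754 ± 15.9 CPM. STAT3 targets were lower in 15 of 23 members, with Fos, Myc, Batf and Hif1a higher (adjusted p = 0.00624), and Pim2 was 5.15-fold lower. MYC and ribosome biogenesis genes were lower in 37 of 47 and Myc, Wdr74 and Tfrc higher (adjusted p = 1.16e-05), with Nolc1 2.04-fold lower. Integrated stress response genes were lower in 16 of 23, with Psph and Ppp1r15a higher (adjusted p = 0.00151), and ER folding genes in 16 of 22, with Herpud1, Dnajb9 and Syvn1 higher (adjusted p = 0.000117; 16 lower and 4 higher adjusted over the list alone); Asns was 2.32-fold and Sdf2l1 3.44-fold lower.

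Cell cycle genes were lower in 36 of 50, with Cdca8, Mcm6, Pcna and Ccne2 higher (camera adjusted p = 0.00105; adjusted p = 0.166 with an estimated correlation). Mast cell and myeloid progenitor markers differed in all 16 members, 9 higher and 7 lower, and the test gave lower (adjusted p = 0.0424; adjusted p = 0.120 with an estimated correlation; 0.748 without the filter and 0.34 with the replicate block). Their median was 0.57 and their mean -1.13; the granule protease gene Prtn3 was 21.3-fold and Ms4a3 33.4-fold lower. The ERK list was not called, with 8 of 22 higher and 9 lower (adjusted p = 0.742), although Fos stood at 23.6 ± 1.12 CPM against 0.638 ± 0.494 CPM (SD, n = 4). The interferon, macrophage and receptor lists, none of them called here, also had medians and means of opposite sign.

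Between the lines 6209 of 9540 genes were called in medium, 3021 higher and 3188 lower in ChimP3V3 cells, and 3111 differed at least 1.5-fold (1520 higher, 1591 lower).

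The fifth comparison set the lines against each other under IL-6. Aldh1a1 stood at 762 ± 35.3 CPM in ChimP3V3 and 6.32 ± 2.32 CPM in gp130:IL-6R cells (SD, n = 4, log2 6.90, SE 0.0945, adjusted p = 4.20e-41). Fos was lower in ChimP3V3 cells by a log2 value of -2.19 (SE 0.157, adjusted p = 8.11e-16) and Spp1 by -1.24 (SE 0.0570, adjusted p = 2.82e-22), whereas in medium the mean CPM of both was higher in ChimP3V3 cells. Hbb-bs again had 0 counts in gp130:IL-6R cells against 859 ± 27.1 CPM. In this comparison 5992 genes were called, 2977 higher and 3015 lower, and 3078 differed at least 1.5-fold (1474 higher, 1604 lower). The authors' deposited table holds 3465 genes past its thresholds in medium (1727 higher, 1738 lower) and 3445 under IL-6 (1555 higher, 1890 lower). Each receptor was present in 1 line, so these differences cannot be assigned to the receptor or to the line.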

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

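The tests of explanations were chosen after the results were seen; the counts over other splits of the libraries were planned before.

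The difference of IL-6 responses was called in 2280 genes. The planned 100 draws, which reassigned IL-6 and medium within each line, do not bear on it. They mix or reverse the conditions of a line instead of making the responses equal. Only 1, the real one, gave as many genes, and the median of the others was 0. The highest other draw gave 2210. It kept the gp130:IL-6R groups whole and moved 4 ChimP3V3 libraries, so that both ChimP3V3 groups held libraries of both conditions. It thus sets the gp130:IL-6R response against mixed ChimP3V3 groups. Fitted to its own 8 libraries, each of the other 4 comparisons had 1 of 35 splits, the real one, with as many genes. This argues against chance in how these libraries fell into groups but cannot exclude it. The smallest share such splits can give is 1 of 35. The other splits also mix libraries of both groups on each side, so they are likely to call few genes whenever many genes differ. Chance differences between cultures are not tested by these splits, since nothing in the labels says that the 4 libraries of a group came from separate cultures. The real counts were 4722 for the response of gp130:IL-6R cells (highest other split 0), 2652 for that of ChimP3V3 cells (1), 6068 between the lines in medium (0) and 5834 under IL-6 (0).

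The immediate-early and feedback genes of the ERK pathway responded less in ChimP3V3 cells, with a median difference of -0.90 on the log2 scale. It was -0.79 without the 1 member that had 0 counts in a whole line. A higher starting level that leaves less room to rise can concern only members that started higher, and for the 8 of 22 called higher in ChimP3V3 cells in medium it is argued against as the whole cause, since under IL-6 all but Myc were called lower in ChimP3V3 cells (median -0.72, camera adjusted p = 0.0147 over these 3 tests; adjusted p = 0.0269 with an estimated correlation). A smaller response of all genes alike is argued against as the whole cause: with the gp130:IL-6R response scaled by 0.57, the median was still -0.37 (camera adjusted p = 3.71e-06). Capped counts of abundant genes are argued against by the 18 members with a mean count under 200, whose median was -1.12 (camera adjusted p = 2.13e-11). A difference in signalling between the receptors may contribute and stays open as untested, as does any other difference between the lines, since each receptor was in 1 line.

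Other lists also differed between the lines in their response to IL-6. The median difference was 0.39 for cholesterol synthesis, 0.26 for MYC and ribosome biogenesis, 0.16 for heat shock and 0.094 for cell cycle genes. The last 2 calls were lost with an estimated correlation (adjusted p = 0.0914 and 0.352), and that of cell cycle genes also without the filter (0.113) and with a CPM of at least 5 (0.0713). It was -0.44 for the integrated stress response, -0.32 for p53 targets and -0.17 for ER folding.

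Among named genes, the response was higher in ChimP3V3 cells on the log2 scale by 1.40 for Gria3, 1.32 for Muc13, 1.30 for Cdk6, 1.25 for Col5a1, 1.21 for Scin, 1.05 for Pim1, 1.00 for Atg12 and 0.71 for Gpx1. The differences were -7.20 for Fos, -3.23 for Anxa1, -2.70 for S100a4, -2.01 for Spp1, -1.51 for Klf6, -1.21 for Hexim1, -1.205 for Sqstm1, -1.13 for Junb and -1.07 for Vim. Another 29 named list members were called for the difference.

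Single libraries stood apart from the other 3 of their group in few measures. IL-6 replicate 4 of gp130:IL-6R cells had 11539 genes with a count, against 11366, 11354 and 11385 in the others (gap over range 0.832, above the 95% limit of Dixon's test), the 1 such case in 20 groups of library measures. Among levels of named genes, 22 of 546 groups held such a library, where chance gives 27.3, and at most 4 fell on 1 library, medium replicate 1 of ChimP3V3 cells.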

How the results depend on the processing

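Merged replicates, thinned counts and the removal of genes with a mean count over 800 were chosen after the data were seen; the other alternatives were planned. No called result among the named genes and lists changed sign, and no median size did. Signs of other called genes were not compared. The balance of higher and lower calls turned. For the difference, 51.8% were higher, against 49.4% with RLE and 47.1% with upper-quartile factors, 41.8% without the filter (903 higher, 1257 lower), 42.7% with a CPM of at least 5 (956, 1283), 47.6% with DESeq2, 49.5% without abundant genes, 49.8% at an adjusted p under 0.01 and 39.2% at a fold of at least 1.5. It ranged from 41.6% to 53.1% with 1 library left out, and was 41.9% (881, 1220) without IL-6 replicate 4 of gp130:IL-6R cells. In ChimP3V3 cells 58.7% were higher, against 50.7% without the filter, 50.6% with a CPM of at least 5, 50.2% with only the groups compared and 49.6% without IL-6 replicate 3. In gp130:IL-6R cells 51.5% were higher, against 49.6% without IL-6 replicate 2, 49.8% without medium replicate 3 and 49.8% without abundant genes. Between the lines 48.7% were higher in medium and 49.7% under IL-6, against 52.5% and 51.8% with upper-quartile factors, and 50.2% under IL-6 without replicate 2 of gp130:IL-6R cells. The cause was not tested. The counts of called genes stayed within 1.5 times under every alternative except a fold of at least 1.5 (1558 for gp130:IL-6R cells, 510 for ChimP3V3 cells, 1006 for the difference, 3111 between the lines in medium and 3078 under IL-6) and an adjusted p under 0.01 for the difference (1453). These thresholds are stricter by construction. DESeq2 called 3994, 1937, 1564, 5597 and 5348 genes in the same order, and limma 4653, 2716, 2413, 6133 and 6033. With 1 library left out, the counts ranged from 4468 to 4500, 2295 to 2432, 2073 to 2200, 5967 to 6056 and 5712 to 5805, and the same-direction overlap from 1377 to 1536.

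The median sizes moved by more than the SD over the IL-6 libraries, a separate measure that leaves out the medium libraries. The cause was not tested. The response of gp130:IL-6R cells stayed the larger in each alternative given here. Over genes that rose, gp130:IL-6R medians were 0.43 with upper-quartile factors, 0.48 without the filter, 0.45 with a CPM of at least 5, 0.43 with merged replicates, 0.43 with thinned counts and 0.46 without abundant genes. Those of ChimP3V3 cells were 0.22, 0.23 and 0.22 in the first 3. Over genes that fell, gp130:IL-6R medians were -0.38, -0.38, -0.37 and, thinned, -0.40. Those of ChimP3V3 cells were -0.23 with RLE factors and -0.24, -0.26, -0.25, -0.23, -0.23 and -0.23 in the order above. With 1 library left out they ranged from 0.427 to 0.458, 0.216 to 0.249, -0.405 to -0.368 and -0.262 to -0.224. The CPM filter was planned as the stricter one but kept 9828 genes against 9540.

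Of 80 list tests 39 were called; fry, which compares no list with other genes, called 64. ERK genes in ChimP3V3 cells passed with RLE factors (adjusted p = 0.0476). Of 227 named gene results 179 were the same under all alternatives, and of 80 list results 49. The fold threshold ended 43 calls of named genes, and in limma the rise of Hba-a2 in ChimP3V3 cells was lost (adjusted p = 0.164).

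The labels number the replicates of every group, but the numbers did not pair the libraries: deviations of 24 same-numbered pairs had a mean correlation of 0.0146 (1 pair above 0.1), and 0 libraries correlated best with their own number in every other group. The replicate block called 4748, 2601, 2254, 6184 and 5957 genes and an overlap of 1556, and changed the calls of 2 lists, NF-kB targets in ChimP3V3 cells (0.0577) and mast cell markers between the lines (0.34). Depth limits low genes: 3 counts over a group correspond to 0.487 to 0.570 CPM.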

Other observations

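The sets of genes and tests in this part were chosen after the data were seen. Among 785 gene ontology terms, the cytoplasmic translation genes rose under IL-6 in 74 of 82 members in gp130:IL-6R cells (camera adjusted p = 9.01e-15) and in 72 in ChimP3V3 cells (adjusted p = 6.46e-31), calls that were lost with an estimated correlation (adjusted p = 0.433 and 0.21). Mitochondrial translation genes fell in 64 of 95 members (adjusted p = 1.92e-06) and 23 members (adjusted p = 3.2e-05). Genes of mRNA splicing fell in 70 and 42 of 134 (adjusted p = 5.82e-05 and 0.00023). Both terms held with an estimated correlation (adjusted p from 0.00927 to 0.0234). Genes of the tricarboxylic acid cycle fell in 14 and 13 of 26 (adjusted p = 0.0203 and 9.87e-05; adjusted p = 0.19 and 0.0591 with an estimated correlation). Between the lines in medium, protein N-linked glycosylation genes were lower in ChimP3V3 cells in 26 of 38 members (adjusted p = 0.00348; adjusted p = 0.124 with an estimated correlation).

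Some genes were almost confined to 1 line in these libraries. With a mean CPM above 40 in both conditions of a line and under 1 in the other, 33 genes marked gp130:IL-6R cells, among them Gdf3, Hook1, Fmr1, Il18r1, Erg and Spry2, and 14 marked ChimP3V3 cells, among them Elf4, Rgs1, Pf4 and Clu. The 33 genes had 39378 counts in their own line and 51 in the other (0.130%), and the 14 had 21519 and 11 (0.0511%).

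Genes of the erythroid and megakaryocyte list were high in ChimP3V3 cells. Reads shared between globin copies move only among these copies, and Hbb-bs had 6418 counts in ChimP3V3 and 0 in gp130:IL-6R cells. This argues against such sharing as the cause of the difference between the lines. The 6 tested members that are not globins, Pf4 among them, were also all higher, with a median of 1.13 (log2). Their levels do not test the sharing of globin reads. Other cells mixed into the cultures are not weighed here. These, an erythroid program of the cells themselves, and whether the pattern comes with the receptor or the line stay open, since the design does not separate the receptor from the line.

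Abundant genes held a small share of the counts. Independent draws of reads are argued against by replicates that differed less than sampling noise: for genes with 600 to 1600 counts per pair, the median chi-square per degree of freedom was 0.902 and 19 of 24 pairs lay under 1 (simulated draws 1.01). A limit on the counts of abundant genes, such as counting reads that share a position once, may be the source: within groups their log-log slope on the library total was 0.645 (SE 0.0409, 227 genes; simulated draws 0.991). No biological explanation was tested, and the counting settings were not given in the sources used here.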
